A study of Homo sapiens with 87 samples.

How the data were processed

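RNA from human peripheral blood mononuclear cells (PBMC; the lymphocytes, monocytes and other mononuclear cells of blood) was measured on 87 Affymetrix oligonucleotide arrays, 1 array per sample. The labels put 84 samples in 9 groups. There were 12 samples seronegative for HIV-1, 22 seropositive samples from a drug-naive set (4 of low, 14 of medium and 4 of high viral load), 10 seropositive samples of a set used to test infection status, and 40 seropositive samples followed by the course of their CD4 T cells. Of the last, 10 and 13 came from the first and second time point of a falling CD4 course, and 9 and 8 from the first and second time point of a rising one. The labels call 3 further samples a test of the CD4 trend without giving the trend, so these entered no comparison. Nothing in the labels says whether samples of a group came from separate donors, so p-values measure the spread between these samples only, which may in part be technical.

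The deposited table held 1 linear intensity per probe set and array, for 8793 probe sets. The steps that made these intensities, from scanner image to probe set value, are not given in the sources used here. The deposited intensities themselves showed a scaling: the mean after leaving out 2% of probe sets at each end lay between 500.087 and 500.852 on every array. Scaling by 1 factor does not align the spread of arrays, and the interquartile range of log2 intensity ran from 1.51 to 3.58. The intensities were therefore taken to log2 and quantile normalized over the 87 arrays, after which values under 16 were set to 16. Of the values kept, 0.996% were at this floor. Quantile normalization gives every array the same distribution, so differences are relative to the other probe sets of an array. In the comparison of drug-naive with seronegative samples, the median over all probe sets was -0.04 with quantile normalization and 0.12 with the deposited scaling. It moved by more than 0.1 also for high and medium against low viral load (0.09 and 0.05 to -0.02 and -0.06), the status test set against drug-naive samples (0.06 to -0.10) and the second rising time point against seronegative samples (0.02 to 0.12).

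Left out were 47 control probe sets and 23 probe sets of XIST or Y chromosome genes. Of the rest, the share of 0.25 with the lowest mean over all arrays was left out, which left 6542 probe sets. Names came from the platform's annotation of 2016, in which 7846 probe sets had 1 gene symbol, 388 had several and 518 had none; no gene was named from a probe set with several symbols, except as a family. Several kept probe sets belonged to the same gene for 90 genes. In the comparison of drug-naive with seronegative samples, 22 of these 90 had a call, and 5 of the 22 had probe sets of opposite sign. No array was identical to another, and the highest correlation between 2 arrays was 0.940.

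Each comparison was a contrast in 1 linear model with a mean per group over the 84 arrays, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate). Differences are log2 values ± the standard error from this fit, and every adjusted p of a gene is limma's, adjusted by Benjamini and Hochberg over the 6542 probe sets with a threshold of 0.05. Other errors are SD, as stated beside them. Genes were named by a fixed rule: the 10 highest and 10 lowest log2 differences among probe sets past the threshold that had 1 symbol, the 3 members of each gene list with the smallest p, and CD4, CD8A and CXCR4. Where none passed, the 3 highest and 3 lowest moderated statistics were named, as values. For 2 further genes of the rule, no probe set was named here. Genes of the HLA, globin, histone and immunoglobulin families were named as families, since a probe set can match several members.

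Groups of genes came from 21 lists: interferon response, pan T cell, naive and CD4 T cell, CD8 and cytotoxic lymphocyte, NK cell, B cell, plasma cell and immunoglobulin, monocyte, neutrophil, erythroid, platelet, dendritic cell, proliferation, T cell activation and checkpoint, immediate early and handling, heat shock, HIV entry, restriction and dependency, apoptosis, ribosomal protein, oxidative phosphorylation, and proteasome. A gene was represented by its brightest probe set. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation, with adjustment over the 21 lists. The preset correlation was too small for these arrays. In 100 random regroupings of the 34 arrays of the comparison of drug-naive with seronegative samples, camera at 0.01 called a median of 5 of the 21 lists and at most 9, against 10 in the true grouping, while the estimated correlation called a median of 0. After this was seen, a test with arrays as the unit was added, here called the array-level test. The mean level of a list on each array was compared between groups by a two-sided permutation test of the difference in means, exact where a group had fewer than 10 arrays and of 100000 resamples otherwise, with adjustment over the 21 lists.

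The status score used the 50 probe sets with the largest absolute moderated statistic between drug-naive and seronegative samples. It is the mean over them of the signed distance from the midpoint of both class means, divided by the difference of these means, so a value above 0 is nearer the drug-naive mean. For an array of either class, selection and means were repeated without that array. The trend score did the same between falling and rising CD4 courses. Shares of arrays carry exact 95% binomial intervals (Clopper-Pearson).

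RNA quality was read from the control probe sets at the 3 prime and 5 prime ends of the GAPDH and ACTB transcripts, whose ratio rises when RNA is degraded, and from the median and interquartile range of each array. These 40 tests formed a family. Control probe sets also showed a hybridization batch that the labels do not give. The bacteriophage cre transcript, a control spiked into the hybridization mix, gave 14.05 to 19.65 (log2) on 51 arrays and 2.31 to 8.12 on the other 36. All arrays of the drug-naive and status test groups and 4 seronegative arrays lacked it, and all arrays of the CD4 course groups, 8 seronegative arrays and the 3 samples without a group had it. Comparisons with the seronegative samples were therefore repeated within the batch and with the batch as a block. Each seropositive group lay in a single batch, so both gave the same differences and varied only in the estimate of error. They are not separate checks of a difference. Every other comparison lay within a single batch as marked by the cre signal. This does not exclude other differences in processing. The control signal of 18S ribosomal RNA was higher by 4.45 (log2) at the second than at the first falling time point.

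The alternatives planned before the data were examined were the deposited scaling, a floor of 64, no filter, and a filter on the lower 0.5 of probe sets. Planned as well were a fit on the compared groups alone, the replicate number as a block, the GAPDH ratio as a covariate, array weights, other numbers of probe sets in the scores, and leaving out each replicate of the groups of 4. Added after the data were seen were the hybridization batch, the removal of 3 arrays of compressed range (interquartile range under 2.2) or of 11 arrays with a GAPDH ratio above 3, the signal of 18S ribosomal RNA as a covariate, the array-level test, and leaving out each array of the larger groups, or any array from the level of a list.

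The test was checked on simulated data with the real design, normal errors and each probe set's own spread over 6542 probe sets, of which 100 were changed by 1 and 100 by 2 on the log2 scale. Of those changed by 2, it recovered 97% in the comparison of drug-naive with seronegative samples, 48% for high against low viral load, 75% for medium against low, and 72% for high against medium. It recovered 92% and 89% for time in the falling and rising courses, 92% and 89% for falling against rising at the first and second time point, 59% for the interaction, 93% for the status test set against seronegative samples and 96% against drug-naive samples. At a change of 1, the recovered shares were 59%, 9%, 22%, 17%, 38%, 35%, 33%, 38%, 9%, 33% and 49% in the same order. In each comparison, 2 to 14 of the unchanged probe sets were called as well. Each probe set had 1 spread over all simulated arrays, so the check held no arrays of compressed range or unequal quality. On the real arrays, random regroupings also gave calls, in 29 cases for high against low load and 69 for medium against low. The recovered shares may therefore not carry over to the real arrays. The number of arrays limits the precision of every value.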

Results

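Expression was measured in PBMC of 12 samples seronegative for HIV-1 and 72 seropositive samples, and 3 further samples had no group. The seropositive samples fell into 22 drug-naive samples (viral load low in 4, medium in 14 and high in 4), 10 samples of a set used to test infection status, and 40 others. These 40 were taken along a CD4 T cell course (falling, 10 and 13 at the first and second time point; rising, 9 and 8). Median deposited intensity per array ran from 156 to 379, and the median correlation of an array with the others had a median of 0.841 and a lowest value of 0.263.

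The first question was how PBMC of drug-naive seropositive samples differed from those of seronegative samples. The largest differences were in heat shock genes. HSPB1, a small chaperone that binds unfolding proteins, was lower by a log2 difference of -4.95 ± 0.48 (31.0-fold; adjusted p = 8.8e-13). Its mean was 6.11 in 22 drug-naive and 11.06 in 12 seronegative samples, and it lay under the seronegative mean in 22 of 22 samples. A probe set of several HSP70 genes, the main inducible chaperones, was lower by -5.03 ± 0.48 (32.7-fold; adjusted p = 8.8e-13), and a second such probe set by -3.24 ± 0.44. DNAJB1, a cochaperone of HSP70, was lower by -2.59 ± 0.33 (adjusted p = 1.0e-08, 22 of 22 samples). In the other direction, CD8A, a chain of the CD8 coreceptor of cytotoxic T cells, was higher by 1.03 ± 0.27 (adjusted p = 0.0068, 18 of 22 samples).

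Of 6542 probe sets, 764 passed the threshold between drug-naive and seronegative samples, 250 higher and 514 lower, and 418 of them differed more than 2-fold. With the deposited scaling in place of quantile normalization, 959 passed, 534 higher and 425 lower, so the split depended on the scaling (32.7% against 55.7% higher), while 594 of the calls were shared. Among the 4 seronegative and 22 drug-naive arrays of the same hybridization batch, 37 passed (4 higher, 33 lower), 36 of them shared with the 764. With the batch as a block, 79 passed, of which 74 were shared.

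The lower end also held genes of stress, inflammation and early response. FOSL2, a subunit of the AP-1 transcription factor, differed by -3.78 ± 0.46 (22 of 22 samples) and SGK1, a kinase induced by glucocorticoid and osmotic stress, by -3.24 ± 0.42 (22 of 22). CXCL8, the chemokine that draws neutrophils, differed by -3.45 ± 0.71 (adjusted p = 0.00041, 21 of 22). The monocyte genes AQP9, a glycerol channel, and NLRP3, the sensor of an inflammasome, differed by -2.78 ± 0.46 and -2.70 ± 0.43 (22 of 22 each). THBS1, a matrix glycoprotein released by platelets and monocytes, differed by -2.66 ± 0.48, the protease inhibitor TIMP2 by -2.57 ± 0.45 and the mitochondrial cyclophilin PPIF by -2.56 ± 0.41 (21 of 22 each).

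At the upper end, DTYMK, a kinase that makes precursors for DNA synthesis, was higher by 2.34 ± 0.36 (adjusted p = 2.3e-06, 21 of 22 samples). IFI27, an interferon-induced mitochondrial protein, was higher by 1.84 ± 0.62 (adjusted p = 0.0388, 20 of 22). The chromatin remodelling subunit BCL7A was higher by 1.91 ± 0.39 (22 of 22) and the PI3 kinase subunit PIK3R3 by 1.78 ± 0.41 (21 of 22). TLX3, a homeobox factor, GH1, growth hormone, ZNF443, a zinc finger protein, SLCO1A2, an organic anion transporter, CLUL1, a clusterin-like protein, and PTGIS, prostacyclin synthase, were higher by 2.11, 1.84, 1.58, 1.57, 1.56 and 1.55. Of the 20 genes named by size, 7 passed the threshold within the hybridization batch, which uses 26 of the same 34 arrays: DTYMK (2.15), SLCO1A2 (2.58), HSPB1 (-5.29), FOSL2 (-3.94), SGK1 (-3.69), DNAJB1 (-3.01) and PPIF (-3.03). Of the 13 that did not pass there, AQP9 (-3.14, adjusted p = 0.0727), THBS1 (-2.69, adjusted p = 0.101), TLX3 (2.63, adjusted p = 0.165), ZNF443 (1.77, adjusted p = 0.203) and IFI27 (2.28, adjusted p = 0.386) had differences at least as large as over all arrays. Others were smaller, such as CLUL1 (0.27, adjusted p = 0.964), BCL7A (0.62, adjusted p = 0.781), GH1 (0.94, adjusted p = 0.834) and PTGIS (1.02, adjusted p = 0.807). CD4 differed by -0.47 ± 0.23 (adjusted p = 0.168, lower in 16 of 22) and CXCR4, the HIV coreceptor, by -0.40 ± 0.24 (adjusted p = 0.289), neither past the threshold.

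As a group, the heat shock list was lower. Of 13 measured genes, 11 passed over all genes, all lower, and 13 did adjusted over the list alone. The median was -1.47 (camera adjusted p = 3.4e-20, and adjusted p = 9.9e-05 with an estimated correlation). The mean level of the list per array was lower by -1.78, in 22 of 22 samples (array-level test, adjusted p = 0.00021), and by -2.03 within the hybridization batch (adjusted p = 0.0014). HSPH1 and HSPD1, chaperones of cytosol and mitochondria, differed by -2.48 and -1.47. In all, 72 of 72 seropositive samples lay under the seronegative mean of this list.

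**Figure D1:**
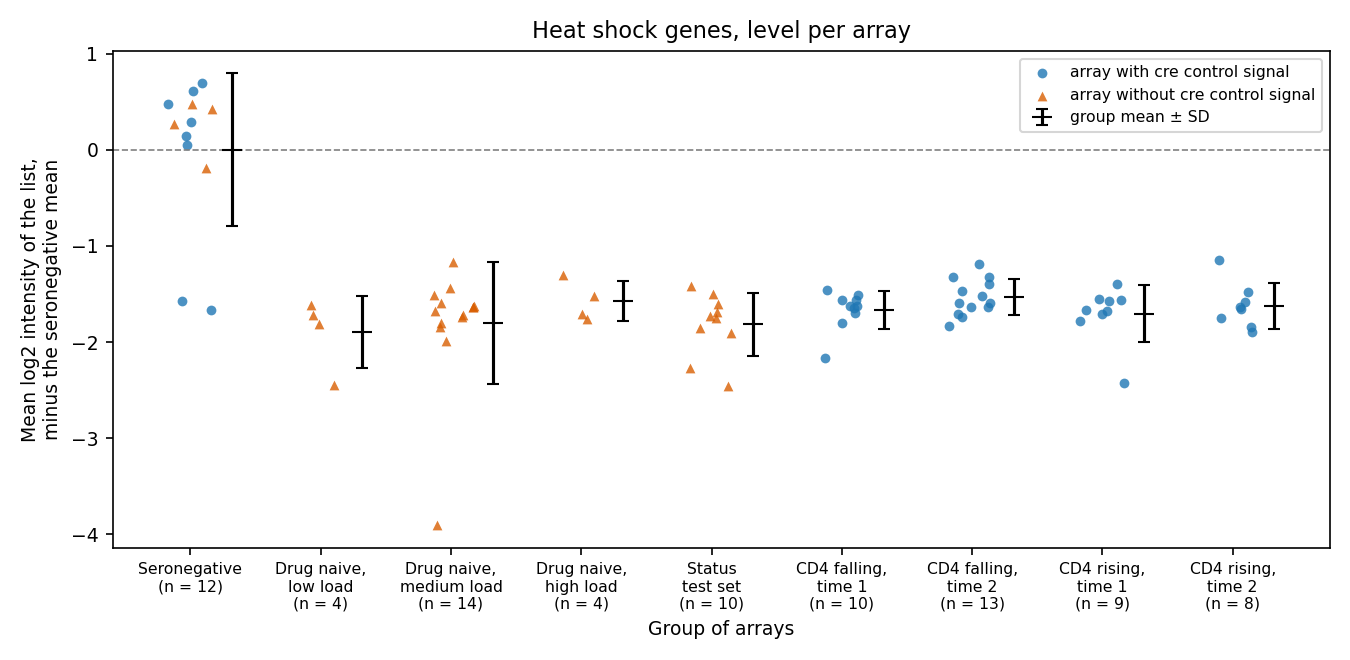
Mean log2 intensity of 13 heat shock genes per array, minus the seronegative mean (vertical axis), in 9 groups; each point is an array, marked by its cre control signal, and the bar is the group mean ± SD. Group means of seropositive samples ran from -1.90 to -1.54, and the seronegative samples had an SD of 0.79.

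Of 34 immediate early and handling genes, which respond within minutes to hours to stimuli and to blood handling, 17 were lower and 0 higher (20 lower adjusted over the list alone). The median was -1.10 (camera adjusted p = 5.5e-09; adjusted p = 0.216 with an estimated correlation). Its level was lower by -1.01 in 21 of 22 samples (array-level adjusted p = 0.00042; within the batch -1.15, adjusted p = 0.0253). Its named genes were PLAUR, the urokinase receptor, at -1.84, THBD, thrombomodulin, at -2.47 and ZFP36, which degrades cytokine transcripts, at -1.68. In the monocyte list, 8 of 18 genes were lower and 0 higher (15 lower adjusted over the list alone), with a median of -0.79 (camera adjusted p = 1.2e-06; adjusted p = 0.216 with an estimated correlation). The list was lower in 20 of 22 samples (array-level -0.87, adjusted p = 0.0029), and within the batch by -0.90 with an adjusted p of 0.148. The differentiation factor CEBPB (-1.64), the endotoxin coreceptor CD14 (-1.45) and the GM-CSF receptor CSF2RA (-1.43) were its named genes.

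Cytotoxic lymphocyte and proliferation genes moved the other way. Of 20 CD8 and cytotoxic genes, 7 were higher and 0 lower (9 higher adjusted over the list alone). The median was 0.66 (camera adjusted p = 1.2e-06; adjusted p = 0.216 with an estimated correlation; array-level 0.58, adjusted p = 0.0288, higher in 18 of 22). Within the batch the array-level difference was 0.73, higher in 20 of 22, but did not pass (adjusted p = 0.165). They included the chemokine CCL5 (1.37), the granule protease GZMA (1.18) and the cystatin CST7 (0.84). Of 25 proliferation genes, 5 were higher and 0 lower (14 higher and 1 lower adjusted over the list alone), with a median of 0.55 (camera adjusted p = 1.2e-06; adjusted p = 0.0851 with an estimated correlation). This list was higher in 21 of 22 samples (array-level 0.54, adjusted p = 0.00098; within the batch 0.58, adjusted p = 0.0368). Its named genes were PTTG1 (0.89), the securin that restrains separase, RRM2 (1.37), which makes deoxynucleotides, and CCNB2 (1.46), a mitotic cyclin.

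Further lists were lower. Platelet genes had 5 of 18 lower, among them CD9 (-1.81) and CAVIN2 (-1.44), and 7 adjusted over the list alone. The median was -0.59 (camera adjusted p = 0.0004, adjusted p = 0.327 with an estimated correlation; array-level -0.82, adjusted p = 0.0043, 19 of 22 samples). Dendritic cell genes had 3 of 9 lower, an HLA class II gene (-0.66), IRF8 (-0.59) and SERPINF1 (-1.37), and 4 adjusted over the list alone. The median was -0.59 (camera adjusted p = 0.047, adjusted p = 0.216 with an estimated correlation; array-level -0.50, adjusted p = 0.0043, 19 of 22 samples). B cell genes had 1 of 15 lower, CD37 (-0.93), and 0 adjusted over the list alone by limma. Their median was -0.47 (camera adjusted p = 0.032, adjusted p = 0.464 with an estimated correlation; array-level -0.45, adjusted p = 0.0207, 20 of 22 samples). Apoptosis genes had 6 of 30 lower, led by BCL2A1 (-1.64), GADD45B (-1.24) and TNFRSF10B (-1.27), and 9 adjusted over the list alone. Their median was -0.20 (camera adjusted p = 0.029, adjusted p = 0.319 with an estimated correlation; array-level -0.39, adjusted p = 0.0122, 18 of 22 samples). NK cell genes (array-level -0.46, adjusted p = 0.0262, 18 of 22 samples) had CD160 higher (1.00) and CD7 lower (-1.50), 1 higher and 5 lower adjusted over the list alone, and a camera adjusted p of 0.096. Neutrophil genes, with CSF3R (-1.26) and FPR1 (-1.16) lower and 3 lower adjusted over the list alone, had a median of -0.01 and a mean of -0.20 (array-level adjusted p = 0.0403, 17 of 22 samples; camera adjusted p = 0.61). Within the batch, the dendritic (-0.60, 20 of 22 samples) and neutrophil (-0.40, 21 of 22) lists passed the array-level test (adjusted p = 0.0368 each). The platelet (-0.44), B cell (-0.27), apoptosis (-0.44) and NK cell (-0.29) lists did not, with adjusted p of 0.41, 0.534, 0.165 and 0.551.

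Interferon response genes were mixed. Of 41 genes, 4 were higher and 1 lower, both over all genes and adjusted over the list alone. The median was 0.15 (camera adjusted p = 0.026; adjusted p = 0.634 with an estimated correlation; array-level 0.20, adjusted p = 0.443, higher in 13 of 22 samples). Within the batch the median was -0.06. IFITM1, which blocks virus entry, differed by 0.82, the ubiquitin enzyme UBE2L6 by 0.45 and the scramblase PLSCR1 by -1.10. Pan T cell genes had CD3D (1.15) and CD2 (0.89) higher and CD7 lower, 2 higher and 2 lower adjusted over the list alone, with a median of 0.42 (camera adjusted p = 0.10). Naive and CD4 T cell genes had MYC (-1.46) lower, 2 lower adjusted over the list alone, and a median of -0.13 (camera adjusted p = 0.61). Plasma cell, erythroid, activation, HIV factor, ribosomal, oxidative phosphorylation and proteasome lists had camera adjusted p values of 0.41, 0.83, 0.61, 0.81, 0.93, 0.82 and 0.93. Their medians were 0.09, 0.08, -0.29, -0.31, -0.05, -0.06 and -0.07, where the ribosomal and proteasome tests pointed upward against a negative median. Genes past the threshold in these lists included TNFRSF9 (1.09), an activation receptor, CD74 (-0.80), the invariant chain, and CXCL12 (1.09), the ligand of CXCR4. Others were CDK9 (-1.38), the kinase that HIV Tat recruits, the respiratory chain subunits NDUFA9 (0.55) and NDUFS1 (-0.77), and the proteasome subunit PSMD2 (0.59).

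**Figure D2:**
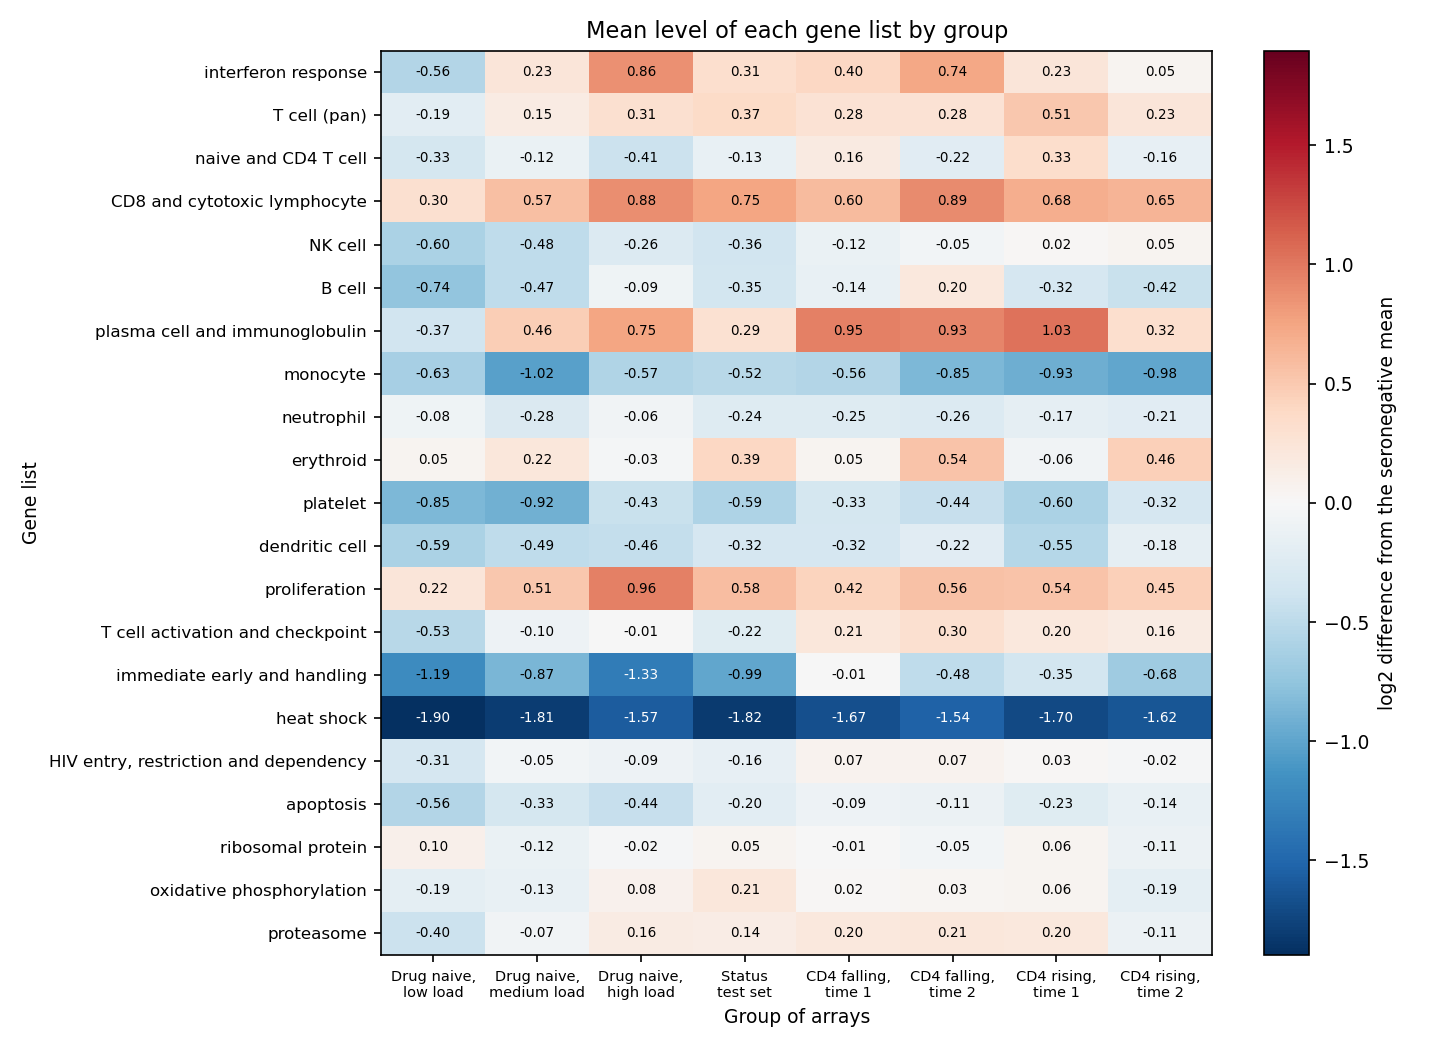
Mean level of 21 gene lists (vertical axis) in 8 seropositive groups (horizontal axis), as log2 difference from the mean of 12 seronegative samples; colour and the printed number give the value. Heat shock was lowest in each group, and the CD8 and cytotoxic list ran from 0.30 in drug-naive low viral load to 0.89 at the second time point of the falling CD4 course.

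The second question was what differed with viral load among drug-naive samples. Between 4 samples of high and 4 of low load, interferon-induced genes were among those with the highest differences. IFI44L, an interferon-induced protein of the cytosol, differed by 4.53 ± 1.19 (adjusted p = 0.0456), and the RNA sensor IFIH1 by 3.17 ± 0.79 (adjusted p = 0.0313). The GTPase GBP1 differed by 2.83 ± 0.69 and IFIT3, which binds other antiviral effectors, by 2.68 ± 0.60 (adjusted p = 0.0176), and all 4 genes were higher in 4 of 4 samples. Also higher were the ATP-gated channel P2RX7 (2.73), the mitochondrial enzyme YARS2 (2.65), the cell cycle inhibitor CDKN2A (2.64), ZMYM3 (2.63), PLAGL1 (2.62), the peptidase THOP1 (2.62) and the replication helicase subunit MCM5 (2.28). SLC6A11, a GABA transporter, was lower by -3.13 ± 0.74 and TARBP1, an RNA methyltransferase, by -1.54 ± 0.41. In all, 47 probe sets passed, 45 higher and 2 lower, and 824 had an unadjusted p under 0.05; with the deposited scaling 0 passed limma's threshold and 611 had an unadjusted p under 0.05. Without replicate 2 of the low load group, an array of compressed range, 2 passed. The plasma cell gene JCHAIN (2.90, adjusted p = 0.0593), CD38 (2.60, adjusted p = 0.0671), CD8A (0.75, adjusted p = 0.60) and CD4 (0.47, adjusted p = 0.728) did not pass.

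In the interferon list, 5 of 41 genes were higher for high against low load, and 20 adjusted over the list alone. The median was 1.20 (camera adjusted p = 8.8e-17; adjusted p = 0.0684 with an estimated correlation). The level per array was higher by 1.42, in 4 of 4 samples, with an exact permutation p of 0.0286, the smallest two-sided value 4 against 4 samples allow, and an adjusted p of 0.15. The proliferation list (median 0.63, camera adjusted p = 0.0018, adjusted p = 0.532 with an estimated correlation) had 1 gene higher and 3 adjusted over the list alone. The proteasome list had 0 of 28 genes past limma's threshold and a median of 0.47 (camera adjusted p = 0.016; adjusted p = 0.811 with an estimated correlation). Most of it came from a single array: the difference in level per array was 0.56, and 0.12 without replicate 2 of the low load group.

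**Figure D3:**
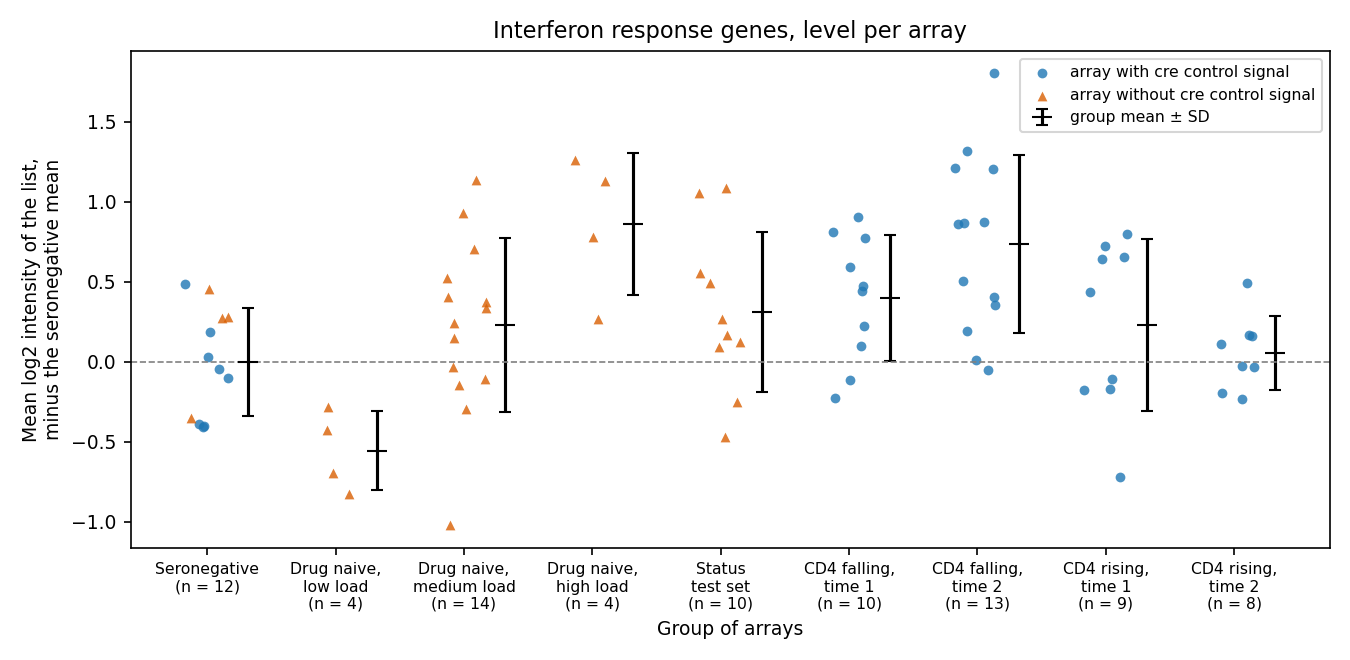
Mean log2 intensity of 41 interferon response genes per array, minus the seronegative mean (vertical axis), in 9 groups; each point is an array, marked by its cre control signal, and the bar is the group mean ± SD. Drug-naive means were -0.56 at low, 0.23 at medium and 0.86 at high viral load, with an array-level adjusted p of 0.15 between high and low, and CD4 course means ran from 0.05 to 0.74.

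Between 14 samples of medium and 4 of low load, CLIC3, a chloride channel protein of cytotoxic cells, was higher by 2.88 ± 0.57 (adjusted p = 0.0021, 13 of 14 samples). THOP1 was higher by 2.63 ± 0.49 (14 of 14) and RACGAP1, needed for cytokinesis, by 2.47 ± 0.41 (adjusted p = 0.0002, 14 of 14). JCHAIN, the joining chain of secreted antibodies, was higher by 2.36 ± 0.64 (adjusted p = 0.0329, 14 of 14) and GBP1 by 2.30 ± 0.56 (13 of 14). The phosphatase PPP4C (2.41), PIAS3 (2.38), which inhibits STAT3, TMEM50B (2.34), HEPH (2.29), the proteasome subunit PSMD3 (2.24), CD38 (2.02), MCM5 (1.78), the interferon-induced ligase HERC5 (1.69), GBP2 (1.56) and the costimulatory receptor CD28 (1.27) were higher. XIAP, an inhibitor of caspases, was lower by -1.85 ± 0.54 (14 of 14). Also lower were KLK12 (-2.14), ZNF137P (-2.02), SLC25A13 (-1.97), ADAM11 (-1.77), CNMD (-1.44), CPQ (-1.44), LRP8 (-1.36), HMHB1 (-1.25) and ALDH3B1 (-1.24). The threshold was passed by 131 probe sets, 118 higher and 13 lower, and by 27 without replicate 2 of the low load group, an array of compressed range. With the deposited scaling 10 passed, all higher, and with the compared groups alone 2.

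The interferon list had 3 of 41 genes higher for medium against low load, and 12 adjusted over the list alone. Its median was 0.64 (camera adjusted p = 1.1e-06; adjusted p = 0.93 with an estimated correlation; array-level 0.79, 13 of 14 samples, adjusted p = 0.202). The monocyte (median -0.56, camera adjusted p = 0.042) and ribosomal (-0.22, camera adjusted p = 0.0023) lists each had an adjusted p of 0.93 with an estimated correlation. Single arrays weighed on these lists: without replicate 11 of the medium load group the difference in level went from -0.40 to -0.22 (monocyte) and from -0.22 to -0.06 (ribosomal). CD8A differed by 1.04 (adjusted p = 0.206) and CD4 by -0.01.

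For high against medium load, 0 probe sets passed limma's threshold and 428 had an unadjusted p under 0.05. With array weights 26 passed, and without the arrays of compressed range 13 did, all of them lower. The most extreme statistics belonged to the mitochondrial import receptor TOMM22 (-2.07 ± 0.49), ALDH1B1 (-1.85 ± 0.45), the phosphatase PPP5C (-1.96 ± 0.51). On the positive side were the TNF receptor TNFRSF1A (1.39 ± 0.41), the calcium binding S100A6 (1.05 ± 0.33) and the calponin CNN2 (0.93 ± 0.31), with adjusted p from 0.35 to 0.519. The camera test called interferon (median 0.57, adjusted p = 7.3e-08), proliferation (0.44, 0.0019), monocyte (0.62, 0.012), platelet (0.47, 0.036) and immediate early (-0.39, 0.0033) lists. With an estimated correlation the first pair had an adjusted p of 0.541 and the other 3 an adjusted p of 0.721. Leaving out a single array took the difference in level from 0.45 to 0.27 for the monocyte list and from -0.46 to -0.28 for the immediate early list.

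The third question concerned the course of CD4 T cells. Over time in the falling course (13 against 10 samples), the naive and CD4 T cell list had a median of -0.37 (camera adjusted p = 1.9e-05; adjusted p = 0.14 with an estimated correlation). Its level was lower by -0.38 in 11 of 13 samples (array-level adjusted p = 0.322). CD4 itself differed by -0.49 ± 0.27. Over the same comparison the control signal of 18S ribosomal RNA was higher by 4.45 in 13 of 13 samples (two-sided permutation test, adjusted p = 0.003) and that of 28S by 2.05 in 13 of 13 (adjusted p = 0.0091). With the 18S signal as a covariate, the median of the naive and CD4 T cell list was -0.35 (camera adjusted p = 0.00061). No probe set passed limma's threshold (0, with 222 at an unadjusted p under 0.05). The most extreme were the ribosome assembly factor NLE1 (-1.34 ± 0.36), the early response gene IER3 (-1.04 ± 0.32), the adaptor GAB2 (-1.42 ± 0.45), and upward ADAM20 (1.37 ± 0.41), PURA (0.73 ± 0.22) and the chromatin reader ZMYND8 (0.73 ± 0.18). The camera test also called the interferon list (median 0.33, adjusted p = 1.3e-05, and adjusted p = 0.488 with an estimated correlation) and the immediate early list (-0.29, adjusted p = 5.2e-08, and adjusted p = 0.414 with an estimated correlation). CD8 (0.37), B cell (0.25), monocyte (-0.26) and erythroid (0.33) lists were called as well, with an adjusted p of 0.414 to 0.501 with an estimated correlation. With the 18S covariate the monocyte (-0.08, adjusted p = 0.328) and erythroid (0.31, adjusted p = 0.0518) calls were lost. With a single array left out, the difference in level fell from 0.29 to 0.15 (CD8), from 0.33 to 0.21 (B cell) and from -0.29 to -0.12 (monocyte).

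Over time in the rising course (8 against 9 samples), CRMP1, a cytosolic phosphoprotein of the semaphorin pathway, was higher by 1.99 ± 0.40 (adjusted p = 0.0233, 8 of 8 samples) and was the single probe set past the threshold. This call was lost with the deposited scaling (2.07, adjusted p = 0.0851), the replicate block (2.00, adjusted p = 0.058), the 18S covariate (1.76, adjusted p = 0.252) and the compared groups alone (1.99, adjusted p = 0.633). The filter on the lower 0.5 of probe sets removed it, and no probe set passed limma's threshold when any of 10 single arrays was left out (0, with 408 to 554 unadjusted). The naive and CD4 T cell list had a median of -0.51 (camera adjusted p = 0.0018; adjusted p = 0.384 with an estimated correlation; array-level -0.49, 7 of 8 samples, adjusted p = 0.188), and CD4 differed by 0.04. A lower level of this list over time was therefore not particular to the falling course. With the 18S signal as a covariate, its interaction of course and time had a median of -0.10 (camera adjusted p = 0.909). Plasma cell (median -0.79), pan T cell (-0.33), immediate early (-0.34), oxidative phosphorylation (-0.22), proteasome (-0.23) and ribosomal (-0.15) lists were called by camera, with an adjusted p of 0.243 to 0.805 with an estimated correlation. The difference in level fell, with a single array left out, from -0.27 to -0.12 (pan T cell), from -0.33 to -0.17 (immediate early) and from -0.17 to -0.11 (ribosomal).

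Between the falling (10) and rising (9) course at the first time point, 0 probe sets passed limma's threshold and 243 had an unadjusted p under 0.05. The most extreme were TRIM16 (-1.62 ± 0.46), the homeobox factor MEIS2 (-1.41 ± 0.44), the ATP synthase subunit ATP5MC1 (-0.83 ± 0.26), the elongation factor ELL (1.68 ± 0.48), the adaptor GAB1 (1.94 ± 0.52) and CRMP1 (1.50 ± 0.38). Pan T cell (median -0.21), monocyte (0.33) and immediate early (0.27) lists were called by camera and had an adjusted p of 0.788 with an estimated correlation. Their differences in level of -0.23, 0.37 and 0.35 fell to -0.15, 0.24 and 0.23 when a single array was left out.

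At the second time point (13 falling against 8 rising samples), interferon-induced genes had the most positive statistics, though 0 probe sets passed limma's threshold and 286 had an unadjusted p under 0.05. IFIT1, which binds viral RNA, differed by 2.56 ± 0.66 and LY6E, an antiviral membrane protein, by 1.94 ± 0.48, each higher in 13 of 13 samples with an adjusted p of 0.506. The liver-type plasma protein ITIH1 differed by 1.52 ± 0.44, the adhesion protein BCAM by -1.49 ± 0.43, THBS2 by -1.50 ± 0.49 and the cytokine IL25 by -1.66 ± 0.57. In the interferon list 0 of 41 genes passed over all genes and 7 did adjusted over the list alone, all higher. Differences were above 0 in 39 of 41 genes, with a median of 0.45 (camera adjusted p = 2.4e-17; adjusted p = 0.0585 with an estimated correlation). The level per array was higher by 0.68, in 11 of 13 samples (exact permutation p = 0.0043, adjusted p = 0.0732). B cell (median 0.59), plasma cell (0.58), proteasome (0.26), CD8 (0.21) and oxidative phosphorylation (0.19) lists were called by camera, with an adjusted p of 0.085, 0.154, 0.708, 0.833 and 0.833 with an estimated correlation. The CD8 difference in level of 0.24 became 0.14 or 0.36 with 1 array left out. The interaction of course and time had 0 probe sets past limma's threshold and 206 at an unadjusted p under 0.05. Most extreme were CRMP1 (-2.36 ± 0.53, adjusted p = 0.167), the creatine kinase CKMT2 (-2.12), KRT1 (-1.70), ITIH3 (2.28), the amino acid transporter SLC7A1 (2.27) and EIF2B3 (1.28).

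Each CD4 course group was also compared with seronegative samples. HSPB1 differed by -3.68 and -3.43 at the first and second time point of the falling course and by -3.90 and -4.20 in the rising one, and CD8A by 1.38, 1.65, 1.45 and 1.27. Within the hybridization batch CD8A differed by 1.31, 1.58, 1.38 and 1.20, the last no longer past the threshold (adjusted p = 0.0523). TNFRSF17, a receptor of plasma cells, was higher by 2.81, 3.17 and 3.09 at falling time point 1 and 2 and rising time point 1. LAG3, an inhibitory receptor of T cells, was higher by 1.95 and 2.24 in the falling course. IFI44L (3.16 ± 0.67) and IFIT1 (2.32 ± 0.59) were higher at the second falling time point in 13 of 13 samples. The thymidylate synthase gene TYMS and the cell cycle factor MYBL2 were higher at the first time point of the falling (1.59 and 2.03) and rising course (1.77 and 2.40). Probe sets past the threshold numbered 64 (17 higher, 47 lower), 145 (54 and 91), 149 (38 and 111) and 112 (31 and 81), in the order falling 1 and 2, rising 1 and 2. With the deposited scaling they numbered 105 (35 and 70), 244 (109 and 135), 212 (73 and 139) and 194 (86 and 108), and with the hybridization batch as a block 26, 62, 65 and 65. Within the batch they numbered 53 (25 and 28), 157 (76 and 81), 146 (54 and 92) and 153 (69 and 84), so lower calls prevailed less, and 37, 99, 99 and 84 of them were among the calls over all arrays. The 4 comparisons used the same 12 seronegative samples, so calls in common are no independent agreement. In all 4 groups 32 probe sets passed, 3 higher (CD8A, PTTG1 and the protease CAPN2) and 29 lower, among them HSPB1, HSPH1, HSPD1, DNAJB1, BAG3, FOSL2, HBEGF, VEGFA, C5AR1, TREM1, PLAUR and HMOX1.

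The heat shock list was lower in each of the 4 groups against seronegative samples, with medians of -1.40, -1.29, -1.55 and -1.22. Past the threshold were 8, 8, 10 and 7 of 13 genes (11, 10, 11 and 11 adjusted over the list alone; adjusted p = 5.9e-07, 9.2e-06, 1.8e-05 and 4.3e-05 with an estimated correlation). Against the 8 seronegative arrays of the same hybridization batch, the array-level adjusted p values were 0.0137, 0.0077, 0.0063 and 0.0473. The CD8 and cytotoxic list, with 2, 7, 5 and 3 of 20 genes higher (7, 14, 6 and 7 adjusted over the list alone), was higher by 0.60, 0.89, 0.68 and 0.65 (array-level adjusted p = 0.0168, 0.00077, 0.005 and 0.0086; adjusted p = 0.123, 0.0215, 0.0862 and 0.171 with an estimated correlation). Against the same-batch controls its array-level differences were 0.52, 0.82, 0.61 and 0.57, with adjusted p of 0.0822, 0.0092, 0.0393 and 0.0538. The first and last calls were lost, though their differences stayed nearly as large. The monocyte list was lower by -0.56, -0.85, -0.93 and -0.98 (array-level adjusted p = 0.0275, 0.0024, 0.00098 and 0.0093; adjusted p = 0.329, 0.056, 0.0862 and 0.144 with an estimated correlation). Against the same-batch controls its array-level differences were -0.54, -0.84, -0.91 and -0.97, with adjusted p of 0.0561, 0.0209, 0.0063 and 0.0522. The monocyte list lost the same calls, at nearly unchanged differences. The proliferation list was higher by 0.42, 0.56, 0.54 and 0.45 (array-level adjusted p = 0.0027, 0.00077, 0.0026 and 0.0058; adjusted p = 0.0793, 0.0224, 0.0606 and 0.144 with an estimated correlation), and against the same-batch controls had 0.046, 0.0094, 0.0226 and 0.0473. The interferon list was higher at the second falling time point by 0.74 in 12 of 13 samples (array-level adjusted p = 0.0024; adjusted p = 0.0401 with an estimated correlation). Of its 41 genes, 6 passed the threshold and 18 did adjusted over the list alone. Of the calls in the 4 groups, 47, 99, 96 and 78 were shared with the drug-naive comparison and 0 had opposite sign. With separate controls (4 seronegative arrays without cre signal for drug-naive and 8 with it for CD4 samples), 13, 20, 19 and 17 lower and 1, 1, 1 and 0 higher calls were shared, again with 0 of opposite sign.

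The fourth question was whether the set used to test infection status resembled drug-naive samples. Against seronegative samples (10 against 12), it had lower HSPB1 (-4.64 ± 0.58, adjusted p = 2.9e-08), BAG3 (-3.03 ± 0.38, adjusted p = 2.9e-08), a cochaperone of HSP70, and DNAJB1 (-2.58 ± 0.39). The HSP70 probe set of several genes was lower by -4.56 ± 0.58 (23.5-fold). THBD (-3.73 ± 0.56), FOSL2 (-3.71 ± 0.55), the growth factors HBEGF (-3.10 ± 0.54), VEGFA (-2.86 ± 0.61) and EREG (-2.55 ± 0.51), a histone gene (-2.70) and the complement receptor C5AR1 (-2.53 ± 0.39) were also lower, all in 10 of 10 samples. DTYMK was higher by 2.80 ± 0.43 (10 of 10), a globin gene by 2.77 ± 0.73 (10 of 10), and TNFRSF17 by 2.52 ± 0.68 (10 of 10). The peptidase ERAP2 was higher by 1.94 ± 0.54 (8 of 10), LAG3 by 1.72 ± 0.43 (9 of 10) and CD8A by 1.23 ± 0.32 (adjusted p = 0.0131, 10 of 10). SIL1 (1.89), SLC25A15 (1.84), TAF1C (1.83), ZNF443 (1.81), SNPH (1.79), CCL5 (1.66), RRM2 (1.63), GZMA (1.41), TYMS (1.40), CD3D (1.26), IFITM1 (1.03) and CD2 (1.02) were higher, and FPR1 (-1.35), PRDM1 (-1.12) and the interleukin 7 receptor IL7R (-1.08) lower.

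In this set 333 probe sets passed, 115 higher and 218 lower, and 29 within the hybridization batch, all 29 shared with the 333; without the arrays of high GAPDH ratio, which leaves 5 of the 10, 17 passed. Heat shock (9 of 13 lower, 12 adjusted over the list alone; median -1.34; adjusted p = 4.4e-05 with an estimated correlation) had an array-level difference of -1.82 (adjusted p = 0.00026), and -2.06 within the batch (adjusted p = 0.007). CD8 and cytotoxic genes (6 of 20 higher, 10 adjusted over the list alone; median 0.80; adjusted p = 0.145 with an estimated correlation) had an array-level difference of 0.75 (adjusted p = 0.00021), and 0.90 within the batch (adjusted p = 0.007). Proliferation (6 of 25 higher, 7 adjusted over the list alone; median 0.53; adjusted p = 0.091 with an estimated correlation) had an array-level difference of 0.58 (adjusted p = 0.00021), and 0.62 within the batch (adjusted p = 0.0336). Immediate early genes (8 of 34 lower, 18 adjusted over the list alone; median -1.05; adjusted p = 0.145 with an estimated correlation) had one of -0.99 (adjusted p = 0.00021), and -1.13 within the batch (adjusted p = 0.007). In all, 12 lists passed the array-level test (5 higher, 7 lower) and 6 did within the batch (3 and 3). Camera also called pan T cell (0.38), interferon (0.33), oxidative phosphorylation (0.27), platelet (-0.39), monocyte (-0.35) and B cell (-0.36) lists, each with an adjusted p of 0.50 to 0.542 with an estimated correlation.

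Called in both the drug-naive and the status test comparison were 202 probe sets, 56 higher, 146 lower and 0 of opposite sign, against 4.39 and 17.1 for independent lists. The same seronegative samples served both comparisons, which by itself gave a correlation of 0.507 of the differences over probe sets in 100 simulations, with a range of 0.145 to 0.862, so the 0.670 found here lies within what shared controls give. In the same simulations no probe set was called in both (at most 0 by limma). Shared controls were their only source of agreement, so few calls were possible in either comparison. The 0 therefore does not measure how far shared controls raise the 202. With the seronegative samples halved at random between both comparisons (100 draws), the correlation over probe sets, which are not independent replicates, was 0.491 on average and ran from 0.387 to 0.559. On average 5.44 higher and 34.5 lower probe sets were then called in both, with fewer controls in each comparison. These draws mixed both hybridization batches; with the 4 seronegative arrays of the same batch halved, 2 for each comparison, it was 0.380 (0.258 to 0.439).

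Against drug-naive samples (10 against 22), the status test set had 95 probe sets past the threshold, 21 higher and 74 lower. Without the arrays of high GAPDH ratio 8 passed (4 and 4), with the ratio as a covariate 43, and with the compared groups alone 4. The signalling adaptor SH3BP5 was lower by -1.64 ± 0.23 (adjusted p = 2.9e-06, 10 of 10 samples), COX20, an assembly factor of cytochrome oxidase, by -1.77 ± 0.30 (10 of 10). GH1 was lower by -2.05 ± 0.45 and CH25H, an interferon-induced hydroxylase, by -1.88. B3GAT1 (-1.84), ANKRD11 (-1.82), NFAT5 (-1.72), HSD11B1 (-1.69), RYR3 (-1.64), CARTPT (-1.60), IL7R (-1.17) and PRDM1 (-1.01) were lower. The phosphatase DUSP6 was higher by 1.77 ± 0.45, the kinesin light chain KLC2 by 1.76 ± 0.41 and the apoptosis effector BAX by 1.48 ± 0.40 (10 of 10 each). NIF3L1 (1.69), FABP7 (1.62), ARPC4 (1.48), PIGH (1.31), CCDC85B (1.28), DCP1A (1.27) and FAM3A (1.24) were higher as well. The oxidative phosphorylation list (median 0.35) had a camera adjusted p of 0.00035, an adjusted p of 0.979 with an estimated correlation and an array-level adjusted p of 0.877. Its difference in level of 0.32 fell to 0.18 without replicate 11 of the medium load group.

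The status score gave the class of 34 of 34 drug-naive and seronegative samples when each was left out (exact 95% interval 89.7% to 100%). It was above 0 in 10 of 10 samples of the status test set (69.2% to 100%) and in 35 of 40 CD4 course samples (73.2% to 95.8%). Samples of both sets were all seropositive, so these shares do not measure how well new seronegative samples are told apart. Trained on arrays without cre signal alone, the status score gave 26 of 26, 10 of 10 and 36 of 40. With 200 probe sets it gave 33 of 34, 9 of 10 and 29 of 40. Of its 50 probe sets 46 were lower in drug-naive samples. The heat shock list held 6 of them and the immediate early list 7, 2 more were HSP70 probe sets of several genes, and 0 were of the monocyte list. That list measured only 18 genes, and NLRP3, named above as a monocyte gene, was among the 50 and lower. A part of monocyte content in the score is therefore not excluded. For heat shock genes, infection and handling of the blood cannot be told apart here, so the score may in part reflect handling. The trend score, between falling and rising CD4 courses, gave the class of 30 of 40 samples (75%, exact 95% interval 58.8% to 87.3%), 20 of 23 falling and 10 of 17 rising. In 100 permutations of the classes, 3 gave as many (one-sided p = 0.0396), and with 20 probe sets or 200 the score gave 23 and 24 of 40. Whether both time points came from the same donors is not given. If they did, a left-out array had its donor's other array in training, and the interval and the permutations treat dependent arrays as independent, so these shares do not measure success on new donors.

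**Figure D4:**
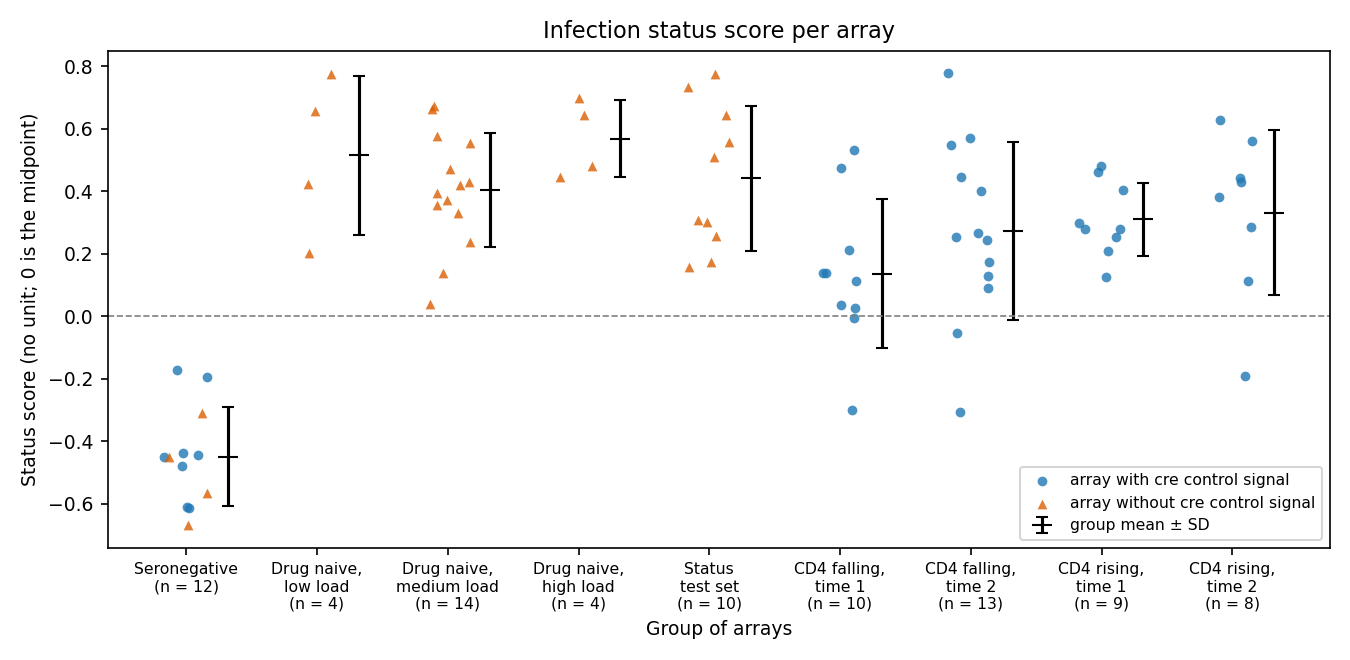
Status score per array (vertical axis, no unit; 0 is the midpoint of both class means) in 9 groups; each point is an array, marked by its cre control signal, and the bar is the group mean ± SD. Scores of seronegative and drug-naive arrays come from scores trained without them, and 10 of 10 status test samples lay above 0.

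RNA quality was compared between the same groups. The log2 ratio of 3 prime to 5 prime GAPDH signal was 0.35 ± 0.47 (SD) in 12 seronegative, 1.12 ± 1.11 in 22 drug-naive and 1.77 ± 1.46 in 10 status test samples. Drug-naive and seronegative samples differed by 0.76 (two-sided permutation test, p = 0.0259, adjusted p = 0.148, higher in 16 of 22 samples), and in ACTB by 1.58 (p = 0.0013, adjusted p = 0.0528, higher in 21 of 22). Status test and seronegative samples differed in GAPDH by 1.41 (p = 0.0039, adjusted p = 0.0575, higher in 7 of 10). Of the 40 tests, 0 passed an adjusted p of 0.05 in these permutation tests. The ratio itself ran from 0.820 to 17.7, and was above 3 on 11 arrays, 5 of them in the status test set.

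**Figure D5:**
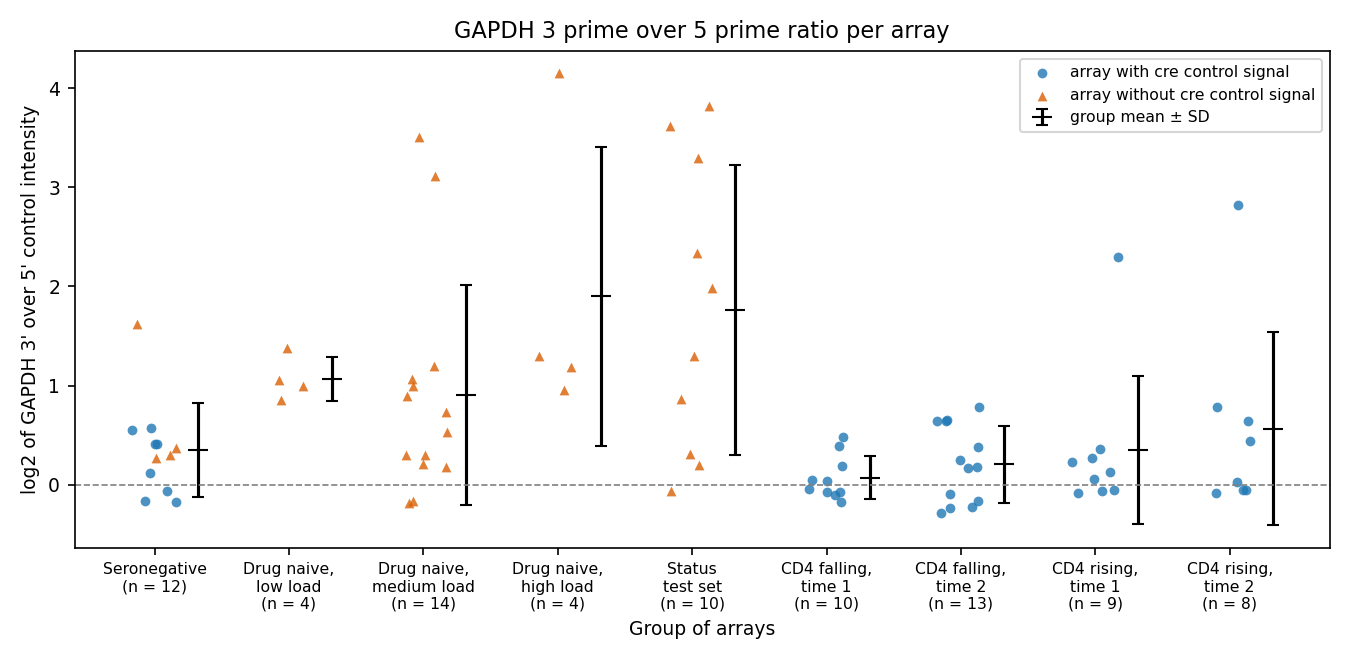
Log2 ratio of 3 prime to 5 prime GAPDH control intensity per array (vertical axis) in 9 groups; each point is an array, marked by its cre control signal, and the bar is the group mean ± SD. The mean was 1.77 in the status test set and 0.35 in seronegative samples.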

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

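Of the tests in this part, those of the hybridization batch, RNA degradation and handling for heat shock genes, of RNA degradation for interferon genes in the CD4 course, and the regroupings within the batch, were chosen only after the result was seen.

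Heat shock genes were lower in seropositive samples, with a median of -1.47 over the list between drug-naive and seronegative samples. The hybridization batch as the whole cause is argued against by a median of -1.95 within the batch, and RNA degradation by -1.55 with the GAPDH ratio as a covariate. A loss of monocytes, which express several of these genes, is argued against as the whole cause by -1.40 with the monocyte level as a covariate (quartiles -2.37 and -0.85), where 9 members were still called. Handling of the blood stays open, since these genes respond to temperature and delay within hours: 2 of 12 seronegative samples lay within the range of the seropositive ones, and the labels give no handling. Handling and infection cannot be told apart here, so lower heat shock expression with infection is a hypothesis and may instead reflect how the seronegative blood was treated.

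Between medium and low viral load, the 131 called probe sets had a median size of 1.58 (log2, in the called direction). With the GAPDH ratio as a covariate it was 1.57. That log2 ratio differed by only -0.16 between these groups (exact permutation p = 0.836). The covariate could therefore hardly move the median and does not decide on RNA degradation. Arrays of compressed range stay open as well. Without the 3 of them the median was 1.25 and 49 probe sets passed, 30 of them among the 131. Without replicate 2 of the low load group, the 1 compressed array of its 4, 27 passed, 16 of them among the 131. An effect of viral load and a compressed array cannot be told apart for these genes, and random regroupings gave as many calls in 26 of 100 cases, with at most 2679.

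Interferon genes were higher in the falling than in the rising CD4 course at the second time point, with a median of 0.45 and an array-level difference of 0.68. With the GAPDH ratio as a covariate the median was 0.45, and with the 18S signal it was 0.45. Between these groups the GAPDH log2 ratio differed by -0.36 and the 18S signal by 0.58 (exact permutation p = 0.261 and 0.617). Covariates without a clear difference between the groups could hardly move the median. They do not decide on RNA degradation or on ribosomal RNA carried into labelling. A single array is argued against by a lowest difference of 0.59 with each array left out. Of the 203490 splits of the 21 arrays, 879 gave a difference as large. This list was 1 of 21 tested, and its array-level adjusted p over them was 0.0732, so chance is not excluded. An interferon response that goes with CD4 loss may be the cause and remains a hypothesis, since viral load and treatment in these groups were not given.

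Random regroupings tested the counts of calls. Over both hybridization batches, 1 of 100 gave as many calls for drug-naive against seronegative samples, the real one (764 against at most 550 in the others). These regroupings mixed the batches while the true groups partly follow them, so they argue against chance but not against the batch. The same holds for the status test set against seronegative samples (1 of 100; 333 against at most 1) and for the CD4 groups against them, each with 1 of 100 (64, 145, 149 and 112 against at most 1, 0, 9 and 5). Within the batch, 3 of 100 regroupings gave as many calls for drug-naive samples (37 against at most 75), a share under 0.05 only when this test is taken alone. There, 1 of 100, the real one, gave as many for the status test set (29 against at most 5). The same held for each CD4 group (53, 157, 146 and 153 against at most 7, 1, 3 and 134). A share of 1 of 100 is the smallest these regroupings allow, and at the second rising time point another regrouping came close. Such a share argues against chance only when each test is taken alone. For the status test set against drug-naive samples, 4 of 100 gave as many (95 against at most 287, and 36 others had calls), a share under 0.05 only when this test is taken alone. Chance cannot be excluded for high against low viral load (3 of 35, with 47 against at most 76), for medium against low, or for time in the rising course (9 of 100, with 1 against at most 21). For high against medium load, time in the falling course, falling against rising at the first and second time point, and the interaction, the real count was 0 with limma (428, 222, 243, 286 and 206 at an unadjusted p under 0.05). Any split reaches a count of 0, so the 100 of 100 splits that did so test nothing, and the others gave at most 1253, 1, 2, 5 and 4 calls. Regroupings with 2679 and 287 calls, several times the real 131 and 95, point to a structure of the samples, which was not itself tested.

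Single arrays lay far from the others of their group in 13 of 150 sets of values, where chance gives about 7.5. All 13 lay in groups of at most 10 arrays, so they do not list every unusual array. Replicate 11 of medium viral load is not among them. Its interquartile range of 1.51 and its median correlation of 0.263 with the other arrays were the lowest of all arrays. Replicate 2 of low viral load had an interquartile range of 1.92 (others 2.75 to 2.80), an oxidative phosphorylation level of -0.90 (others 0.02 to 0.11) and a proteasome level of -1.74 (others -0.10 to 0.12). The GAPDH ratio (log2) was 4.15 in replicate 1 of high viral load (others 0.95 to 1.30), 2.30 in replicate 3 of rising time point 1 (others -0.08 to 0.36) and 2.82 in replicate 1 of rising time point 2 (others -0.08 to 0.79). The ACTB ratio of these 3 arrays was 6.79 (others 1.94 to 2.57), 4.22 (0.55 to 1.40) and 5.42 (0.21 to 2.22). The same high viral load array had a ribosomal protein level of 0.0847 (others -0.07 to -0.05). Replicate 3 of falling time point 1 had a CD8 and cytotoxic level of -0.72 (others 0.40 to 1.22). Heat shock levels were -2.16 in replicate 4 of that group (others -1.80 to -1.46) and -2.43 in replicate 3 of rising time point 1 (others -1.78 to -1.39).

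The change over time differed between falling and rising courses in 7 lists by camera: interferon (median of the difference 0.43, adjusted p = 2.2e-06), CD8 and cytotoxic (0.42, 0.0126), B cell (0.44, 0.0112), platelet (-0.44, 0.0112), ribosomal (0.13, 0.0241), oxidative phosphorylation (0.23, 0.00039) and proteasome (0.26, 0.0051). With an estimated correlation their adjusted p ran from 0.684 to 0.728, and random regroupings called a median of 4 lists and at most 10, so these calls do not exclude chance.

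The control probe set of 18S ribosomal RNA, which was not among the genes compared, had a mean of 12.85 ± 2.28 (SD, log2) at the second falling time point against 8.39 ± 2.00 at the first (permutation test, two-sided, adjusted p = 0.003, higher in 13 of 13 samples). It was 12.27 ± 2.99 against 9.02 ± 2.90 in the rising course (exact permutation test, two-sided, adjusted p = 0.268, higher in 7 of 8), and 9.01 ± 2.18 in seronegative samples.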

How the results depend on the processing

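Alternatives that use the hybridization batch, leave out compressed arrays or arrays of high GAPDH ratio, take 18S signal as a covariate, permute arrays, or leave out single arrays of the larger groups were chosen only after the data were seen. Over all alternatives except single arrays left out, 123 of 188 counts and scores stayed within 1.5 times their value and 65 moved. The 123 include counts of 0 that stayed 0. These came from high against medium load, time in the falling course, falling against rising at both time points, and the interaction. A count of 0 that stays 0 says little, so the 123 overstate the stability of the calls. Of list calls, 709 of 858 held and 149 were lost. With an estimated correlation, 9 of 100 held and 91 were lost. The other alternatives kept the preset correlation, which was too small for these arrays, so the 709 overstate the stability of the list calls. Of gene calls, 2967 of 3707 held, 738 kept their direction without the call and 2 reversed. The reversed gene was RPL9 between drug-naive and seronegative samples, at 0.12 with the batch as a block and at 0.12 within the batch. Both values are the same estimate. With the mean of all probe sets of a gene, 100 of 100 list calls held. Only 90 genes had several kept probe sets, so this alternative could change little. Measures of RNA quality come from the deposited control intensities and gave no value under quantile normalization. The cause was not tested for any of these changes. Signal over background limits genes near the floor, where 0.996% of values lay.

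With the deposited scaling, calls numbered 0 for high against low viral load (limma; 611 at an unadjusted p under 0.05), 10 for medium against low, 1 for high against medium, 0 for time in the rising course (limma; 650 unadjusted) and 1 for the interaction. They numbered 541 for the status test set against seronegative and 249 against drug-naive samples, and 105, 244 and 194 for falling time points 1 and 2 and rising time point 2 against seronegative. A floor of 64 gave 11 for high and 47 for medium against low load. No filter gave 61 for the status test set against drug-naive samples, and leaving out the lower 0.5 of probe sets gave 0 for time in the rising course (limma; 369 unadjusted). A fit on the compared groups alone gave 488 for drug-naive against seronegative samples, 0 for high (limma; 363 unadjusted) and 2 for medium against low load, and 0 for time in the rising course (limma; 467 unadjusted). It gave 658 and 4 for the status test set against seronegative and drug-naive samples, and 204, 454, 478 and 201 for the CD4 groups.

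The GAPDH ratio as a covariate gave 93 and 43 for the status test set against seronegative and drug-naive samples. Array weights gave 1149 for drug-naive against seronegative samples, 12, 39 and 26 for high against low, medium against low and high against medium load, 2 for time in the rising course, and 1 for falling against rising at the first time point. They also gave 654 and 227 for the status test set, and 485, 738, 479 and 413 for the CD4 groups. The batch as a block gave 79 for drug-naive and 55 for status test against seronegative samples and 26, 62, 65 and 65 for the CD4 groups; arrays without cre signal alone gave 37 and 29. Without the compressed arrays, calls numbered 2, 49 and 13 for high against low, medium against low and high against medium load, 678 for the status test set against seronegative samples, and 140, 285, 309 and 268 for the CD4 groups. Without arrays of high GAPDH ratio they numbered 216 for medium against low load, 4 for time in the rising course, 1 for falling against rising at the first time point, 1 for the interaction, and 17 and 8 for the status test set. The 18S covariate gave 0 for time in the rising course (limma; 506 unadjusted). The trend score with 20 probe sets gave the class of 23 of 40 samples.

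With the replicate number as a block, calls numbered 73 for medium against low load, 0 for time in the rising course (limma; 500 unadjusted) and 50 for the status test set against drug-naive samples. The numbers did not pair the samples: after removal of group means, arrays of the same number at both time points had a mean correlation of 0.00754 over 10 numbers in the falling and -0.0413 over 8 in the rising course.

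With single arrays left out, calls ran from 627 to 852 for drug-naive and from 182 to 458 for status test against seronegative samples, the latter 182, 186 and 199 without status test replicates 1, 2 and 7. High against low load ran from 2 to 168: 168, 2 and 101 without low replicates 1, 2 and 3, and 28, 13, 17 and 21 without high replicates 1 to 4. Medium against low ran from 27 to 320: 316, 27 and 212 without low replicates 1, 2 and 3, and 320 without medium replicate 11. The status test set against drug-naive samples ran from 39 to 116: 60 without low replicate 2, 57 and 58 without medium replicates 4 and 14, and 56, 39, 41 and 43 without status test replicates 1, 2, 7 and 8. High against medium ran from 0 to 1 (limma; 242 to 483 unadjusted where 0), with 1 without medium replicate 4 or high replicate 2. Time in the rising course ran from 0 to 2, with 0 (limma; 408 to 554 unadjusted) without replicate 2, 4, 5, 7 or 8 of the first or 1, 2, 4, 6 or 7 of the second time point, and 2 without replicate 3 or 8 of the second. The interaction ran from 0 to 1 (limma; 176 to 237 unadjusted where 0), with 1 without rising replicate 3 of the first or 5 of the second time point. Time in the falling course and falling against rising at the first and second time point ran from 0 to 0 (limma; 158 to 278, 222 to 297 and 160 to 395 unadjusted).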

Other observations

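Comparisons with separate seronegative samples or those of the same batch and the array-level test of lists were chosen only after the data were seen.

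Of 72 seropositive samples, 63 lay above the seronegative mean of the CD8 and cytotoxic list and 69 above that of the proliferation list. Against seronegative samples of the same batch the CD8 and cytotoxic list did not pass the array-level test for drug-naive samples (adjusted p = 0.165), falling time point 1 (0.0822) or rising time point 2 (0.0538). The differences there were 0.73, 0.52 and 0.57, near or above those from all seronegative samples. The monocyte list lay under its seronegative mean in 65 of 72, and platelet, dendritic and immediate early lists in 58 of 72 each. The interferon list lay above its mean in 50 of 72. The plasma cell list, of which 5 of 16 genes were measured, had a higher mean at both falling time points and the first rising one (0.95, 0.93 and 1.03 array-level against seronegative samples, adjusted p = 0.0027, 0.0024 and 0.00057; adjusted p = 0.055, 0.119 and 0.0862 with an estimated correlation). The medians were 0.42, 0.23 and 0.23 and 1, 2 and 1 genes passed the threshold (2 each adjusted over the list alone), so few genes carried these means. Within the batch the array-level differences were 0.81, 0.79 and 0.90, with adjusted p of 0.046, 0.0241 and 0.0063. By camera the call at falling time point 2 was lost with the batch as a block (adjusted p = 0.0712) and within the batch (adjusted p = 0.156).

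Where drug-naive and CD4 course samples were each compared with their own seronegative arrays, 4 without and 8 with cre signal, the differences correlated over probe sets, which are not independent replicates, at 0.316 and 0.353 for falling and 0.417 and 0.410 for rising time points 1 and 2. Shared lower calls numbered 13, 20, 19 and 17 against 0.141, 0.409, 0.464 and 0.424 for independent lists.

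The 3 samples without a group had trend scores of -0.237, -0.380 and 0.0380, where a value above 0 is nearer the falling course. With 20 probe sets the scores were -0.173, -0.233 and -0.221, with 200 they were 0.0376, 0.125 and -0.277, and with the deposited scaling -0.299, -0.0437 and -0.189, so the sign differed between settings. Their heat shock levels ran from -2.11 to -1.45 and their interferon levels from -0.75 to 0.70, relative to the seronegative mean.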
